A study of Mus musculus with 6 samples.

How the data were processed

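RNA-seq was analysed from 6 libraries of 5-FU-treated mice, 3 from mice given an elemental diet and 3 from mice given saline, grouped by the title, diet and treatment labels. Per the labels' protocols, polyadenylated RNA was selected with oligo-dT beads and sequenced as paired reads of 75 bp. The same protocol names fibroblasts or keratinocytes as the source of the RNA, while the tissue label names salivary gland; the sources used here do not resolve this. The labels give 3 mice per group, and do not say whether each library is a separate mouse, so p-values measure the spread between these libraries.

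The deposited files, 1 per library, hold 41325 gene rows each. Per the file headers, the authors assigned reads to genes and gave whole-number read counts per gene, split into exon, intron and exon-exon reads, as total and as unique reads. Total gene reads equalled exon plus intron reads in every row. The TPM column, per the file headers, was computed by the authors, and the expression value column repeats it. The RPKM column was made by the authors from total exon reads and exon length, per the file headers; its implied denominator was larger than the reads in the table, which came to 96.4% to 97.6% of it. The aligner, the counting tool, whether strand was used and any filter are not given in the sources used here. The submitters' processing notes name the builds GRCh37 and GRCm38. Of the gene identifiers in the files 41297 were found in the GENCODE M21 annotation of GRCm38, 40469 with the same chromosome, start and end, and the coordinates printed are those of the files.

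Total reads per gene, reads shared between genes and reads in introns included, were the measurement. Library totals ranged from 29053287 to 33073125 per library, of which 86.0% to 87.7% were unique. A count of 0 allows up to 3 reads, and intervals and floors cover counting error only, since the reads carry no molecular identifiers that were used here. Replicates were compared before averaging: Spearman correlations over genes with a mean of at least 1 CPM were 0.993 to 0.997 within groups and 0.816 to 0.829 between groups (across genes, which are not independent replicates). The smallest median chi-square per gene between 2 replicates was 2.97 times that of sampling noise.

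The comparison of elemental diet with saline used edgeR 4.0.16 in R 4.3.3 (glmQLFit with robust estimation, glmQLFTest, two-sided) with TMM scaling and the filterByExpr filter, which left 18303 genes, and Benjamini-Hochberg adjustment at 0.05. Fold changes and standard errors (SE) are on the log2 scale. The SE is approximate, taken as the absolute log2 fold change divided by the square root of the F statistic. CPM values are scaled with the TMM factors. Exceptions are Krt8, the marker figure, read shares, thresholds of 1 CPM in every library and read-based floors, which use library totals. The common biological coefficient of variation was 8.26%. Lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01, with an estimated correlation and fry beside it, two-sided, over 43 lists with at least 5 tested members. Of 919 list symbols 917 were found, 4 of them by identifier and 1 by an older symbol. Principal components used log2 CPM with a prior count of 2. An exact permutation test served for single values, where 3 against 3 libraries cannot go below p = 0.1. The fold of a gene with no read in a group was taken against 3 reads over that group as a lower bound.

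The design, the 43 lists, the alternatives and the rule for naming genes were set before the data were examined. The rule took, from genes past the test with a mean of at least 1 CPM and groups that did not overlap, the 12 with the largest rise and the 12 with the largest fall. It left out clone names, numbered predicted genes, pseudogenes and immunoglobulin or T cell receptor V, D and J segments (498 that rose and 1013 that fell), which are counted only. It also took the 4 members with the smallest p of each called list and of 7 lists tied to the gland, 5-FU, cell division and cell death, then Aqp5, Amy1, Egf, Cdkn1a and Tyms, and the 5 most abundant genes. This gave 99 genes, not all of which are described; the values of 5 of them are not reported here. Further gene lists used in the closing section were drawn up after the data were seen.

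A first self-test of 1 simulation failed its check on false calls; the number of simulations was then raised and the pass criterion was changed to bounds on unadjusted p-values and on recovery at 4-fold. The test was tried on simulated counts for the same 18303 genes with 200 changed genes in 20 simulations. It recovered 20.2% of genes changed 1.2-fold, 55.9% at 1.5-fold, 72.0% at 2-fold and 94.7% at 4-fold, and 10.1% of its calls were false, above the nominal 5%. Of unchanged genes 4.88% had an unadjusted p under 0.05. The moved list was called and 0 of 20 random lists were. No correlation between genes was simulated, so this does not check the preset correlation used for the lists. The 200 changed genes moved in balanced directions, against 14303 genes called in the data. The recovery and the share of false calls may therefore not carry over to the data.

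Alternatives were other scalings (RLE, upper quartile, none, without the 20 most abundant genes), no filter and a stricter filter, no robust estimation, the replicate number as a block, unique reads, DESeq2 1.42.0, limma-voom, limma-trend on log2 TPM with a pseudocount of 1 or 0.1, a test against a fold change of 1.5, and each library left out in turn. Exon reads alone, and all genes but hemoglobin and immunoglobulin genes, were added after seeing the data. RPKM was used only to check how the columns were made. Figures were drawn with matplotlib 3.10.9 in Python 3.11.15.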

Results

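The series held 6 bulk RNA-seq libraries from female mice of the outbred ICR stock, bought at 10 weeks of age and habituated for 7 days. Every mouse was injected with 5-fluorouracil (5-FU), an antimetabolite whose main target is thymidylate synthase, at 20 mg/kg per day on 2 days a week over 3 weeks. The 3 libraries of the elemental diet group came from mice that also received by mouth 1.6 kcal per day of an elemental diet, a liquid formula in which amino acids replace whole protein. The 3 libraries of the saline control group came from mice given the same 0.8 mL per day of saline. The labels name the tissue as salivary gland and do not say which gland. No library came from a mouse without 5-FU, so the only contrast available was elemental diet against saline under 5-FU. Each library held reads for 41325 gene rows, with 29053287 to 33073125 reads assigned to genes. At this depth a gene with no read in a library could still lie at up to 0.0907 to 0.103 CPM (reads per 1e6 reads), which is 3 reads; such limits cover counting error only.

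Transcripts that mark salivary gland were at or near this floor in all 6 libraries. Aqp5, the water channel of acinar cells (GRCm38 chromosome 15, 99590782 to 99594829), had 4 reads in the elemental diet libraries and 2 in the saline libraries. Smgc, Pip, Bpifa1 and Prb1, which encode secreted saliva proteins, had 0 reads in all 6 libraries. Of 27 measured acinar secretory products 11 had no read in any library, 3 reached 1 CPM in every library and 7 had enough reads to be tested. Of 22 measured products of the granular convoluted tubule, the duct segment of the rodent submandibular gland, 8 had no read and 5 could be tested. The simple epithelial keratin gene Krt8 stood at 0.610 ± 0.414 CPM (SD, n = 3) with elemental diet and 0.844 ± 0.801 with saline, and the basal cell keratin gene Krt5 had 2 reads in the elemental diet libraries and 0 in the saline libraries. These genes outside the naming rule were chosen after their values were seen. The tissue label is therefore given below only as the label, and the libraries are referred to as the libraries labelled salivary gland.

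Transcripts of blood-forming and lymphoid cells were abundant in the libraries labelled salivary gland, and their shares differed between the groups. Hemoglobin genes took 3.43% ± 0.121 of reads (SD, n = 3) with elemental diet and 0.370% ± 0.0997 with saline. Immunoglobulin genes took 0.380% ± 0.0389 with elemental diet and 3.30% ± 0.200 with saline. Reads in introns made up 8.64% ± 0.225 with elemental diet and 14.0% ± 0.341 with saline, and mitochondrially encoded genes took 2.89% ± 0.156 and 3.51% ± 0.167. For the intron share the exact two-sided permutation test gave p = 0.1, the smallest value that the 20 arrangements of 3 against 3 libraries can give.

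**Figure D1:**
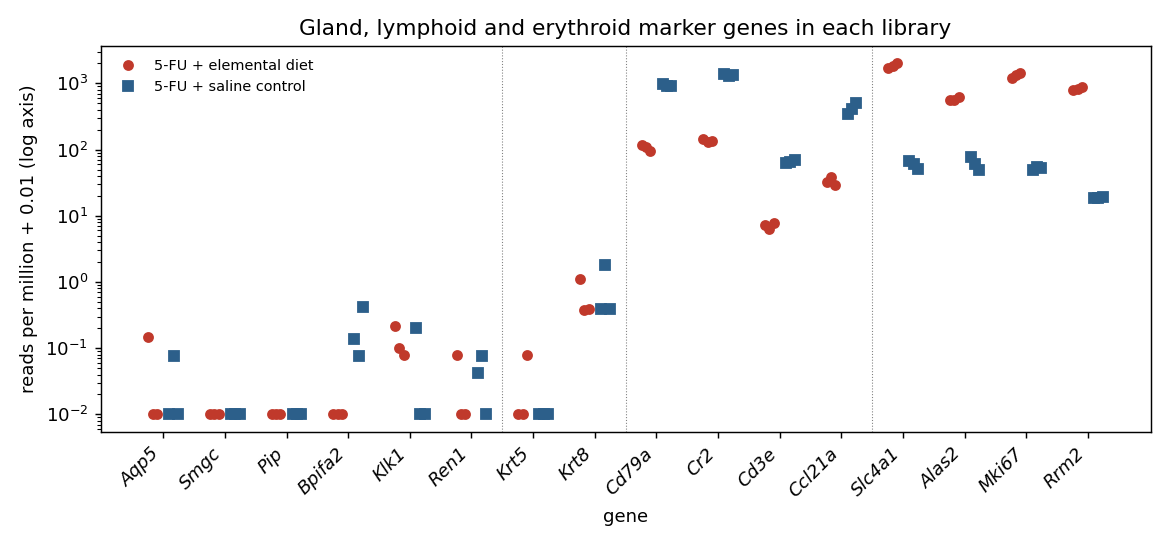
CPM before normalization (plus 0.01, log axis) of 16 marker genes, 1 point per library, with elemental diet as circles and saline as squares. Salivary secretion and tubule genes (Aqp5 to Ren1) and keratin genes (Krt5, Krt8) lie at or near the floor in all 6 libraries, lymphoid genes (Cd79a to Ccl21a) are lower with elemental diet, and erythroid and cell cycle genes (Slc4a1 to Rrm2) are higher.

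The comparison of elemental diet with saline asks which transcripts differ when 5-FU-treated mice receive the diet. Genes of red cell production and of cell division were far higher with elemental diet, and genes of B cells, T cells, plasma cells and antigen presentation were far lower. Slc4a1, the red cell anion exchanger band 3, stood at 2058 ± 204 CPM (normalized, SD, n = 3) with elemental diet and 54.0 ± 7.24 with saline (log2 fold change 5.25, SE 0.13, edgeR adjusted p = 5.3e-09). Rrm2, the small subunit of ribonucleotide reductase, stood at 925 ± 64.4 and 17.0 ± 0.436 CPM (log2 fold change 5.77, SE 0.07, adjusted p = 2.6e-15). Ighm, the constant region of immunoglobulin M, went the other way, with 1085 ± 41.1 CPM with elemental diet and 8724 ± 343 with saline (log2 fold change -3.01, SE 0.05, adjusted p = 6.7e-15). Cr2, the complement receptor CD21 of mature B cells, was lower as well, at 152 ± 3.62 CPM with elemental diet and 1213 ± 27.8 with saline.

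Across the 18303 genes tested with edgeR's quasi-likelihood test, 14303 (78.1%) differed at a Benjamini-Hochberg adjusted p under 0.05, 6951 higher and 7352 lower with elemental diet. Of these, 3487 were over 2-fold higher and 4340 over 2-fold lower, and 555 and 306 passed 10-fold. The 2 groups did not overlap in 14821 genes (81.0%), where chance gives 10%. The balance of directions depended on the scaling. Without composition normalization the test called 5407 genes higher and 9265 lower, and with upper quartile normalization 5601 and 9051; the median log2 fold change of all genes was -0.39 and -0.35 there against -0.08 with the main scaling, so changes of that size have no settled direction. Tested against a fold change of 1.5, the count was 9294. The first principal component held 89.1% of the variance and parted the groups, with an exact two-sided permutation p = 0.1, the smallest possible here, and the second held 4.18%.

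**Figure D2:**
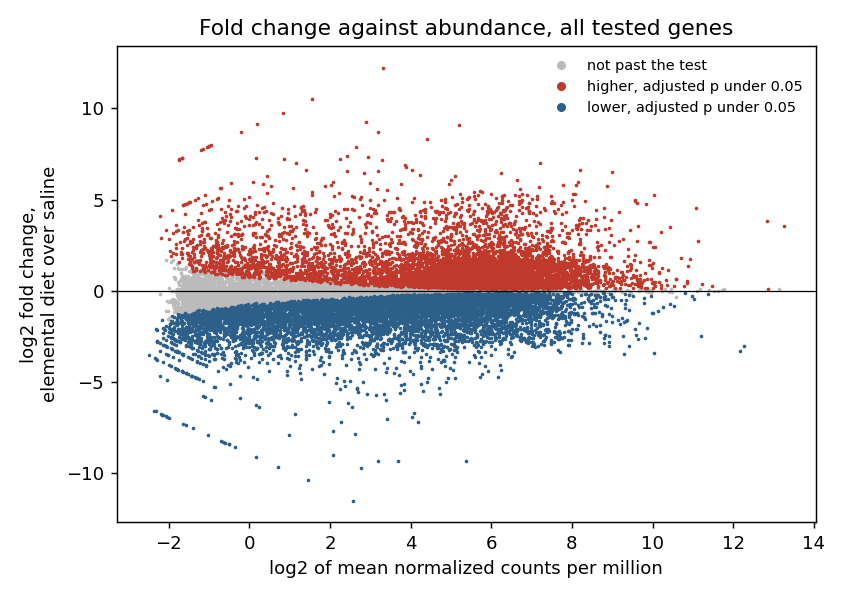
Log2 fold change (elemental diet over saline) against the log2 of mean normalized CPM for the 18303 tested genes, 1 point per gene. Red points are the 6951 genes that passed the test higher, blue points the 7352 that passed it lower and grey points the rest; points in diagonal lines at low abundance are genes with no read in 1 group, whose fitted fold depends on the prior count.

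The 12 largest rises that the naming rule took, among genes of at least 1 CPM, included genes of neutrophil granules, an embryonic globin and a red cell enzyme. Mpo and Elane, the myeloperoxidase and elastase of neutrophil precursors, stood at 73.2 ± 0.993 and 18.2 ± 1.09 CPM (SD, n = 3) with elemental diet and at 0.133 ± 0.181 and 0.0398 ± 0.0345 with saline. Ltf and Ngp, 2 further neutrophil granule genes, and Mcpt8, a protease of basophils, had 1028, 1255 and 872 reads with elemental diet against 5, 9 and 6 with saline. Hba-x, the embryonic zeta globin, had 189 reads against 0 and was at least 77.0-fold higher, taking the saline group at a floor of 3 reads over the group. Pklr, the pyruvate kinase of liver and red cells, stood at 292 ± 19.3 against 2.28 ± 0.365 CPM (log2 fold change 7.00, SE 0.09, adjusted p = 3.5e-15). The remaining genes of this set were Aknad1, the largest rise by fitted fold, Tdrd5, Nkx1-2, Ugt8a and Glp1r, none above 19.3 CPM in either group. With elemental diet 100% of the Glp1r reads lay in introns. For Aknad1 the ratio of reads per effective library was 740 with a 95% exact counting interval of 204 to 6120, since the saline group had 2 reads. With a floor of 3 reads over the saline group it was 493.5, against 565 for Mpo, so the order of these 2 genes is not settled.

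The 12 largest falls that the naming rule took were smaller than the 12 largest rises. Left out by the rule were 1013 genes that fell and 498 that rose. Some of these fell further than the genes named here. The predicted gene Gm47248 stood at 0 CPM with elemental diet and 2.24 with saline. The immunoglobulin V gene Ighv1-34 had 10 reads with elemental diet and 8255 with saline. Trim5 and Trim30d, members of a TRIM gene cluster on chromosome 7, stood at 1.47 ± 0.274 and 3.14 ± 0.278 CPM with elemental diet and at 30.4 ± 0.658 and 63.2 ± 3.50 with saline. Iglc1, an immunoglobulin lambda constant gene, fell 17.7-fold and Wfdc17, a gene of myeloid cells, 17.6-fold. Only 0.0609% of the Iglc1 reads were unique to it, so its share among the lambda genes is uncertain. Prrt4, Gad1os, Dmrta1, Dapl1, Cfap74, Drd5, Gpr83 and Fam186b were also among the 12 falls that the rule took, each at 6.24 CPM or less with saline. With elemental diet 100%, 87.5% and 93.1% of the few Gad1os, Cfap74 and Fam186b reads lay in introns. Gad1os overlaps Gad1 on the other strand, and whether the counting used strand is not given in the sources used here.

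Lymphoid lists fell. All 24 members of the list of B and T lymphocyte and lymph node genes fell, also when adjusted over the list alone, with a median log2 fold change of -2.86. Cd22, an inhibitory receptor of B cells, was 8.28-fold lower, and Ms4a1 (CD20), a B cell surface protein, was 6.09-fold lower. The competitive test, camera with a preset correlation of 0.01, gave an adjusted p = 1.2e-29 for this list, against an adjusted p = 0.139 with an estimated correlation. Of 16 plasma cell genes 15 fell and 1 rose, with the same counts adjusted over the list alone (median -1.89, camera adjusted p = 1.5e-10, adjusted p = 0.200 with an estimated correlation). Besides Ighm and Iglc1 the fall was clearest for Tnfrsf13b, a receptor for B cell survival factors, at 5.97-fold, and Pou2af1, a B cell transcription coactivator, at 4.90-fold. The member that rose was Sdc1, the surface proteoglycan CD138, by 0.88 on the log2 scale, named after its value was seen.

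Antigen-presenting cell and interferon gamma lists fell as well. Of 20 macrophage and dendritic cell genes 17 fell, 1 rose and 2 did not pass, with the same counts adjusted over the list alone (median -1.25, camera adjusted p = 3.3e-07, adjusted p = 0.224 with an estimated correlation). The 4 members with the smallest p were class II antigen presentation genes, which B cells also express. Cd74, the class II invariant chain, stood at 721 ± 47.2 CPM with elemental diet and 3950 ± 88.2 with saline, and H2-Aa, H2-Ab1 and H2-Eb1 were 6.06-fold, 5.27-fold and 6.34-fold lower. The member that rose was Xcr1, a receptor of cross-presenting dendritic cells, named after its value was seen. Of 23 genes of interferon gamma response and antigen presentation 22 fell and 1, Igtp, rose, adjusted over the list alone as well (median -1.34, camera adjusted p = 5.3e-10, adjusted p = 0.164 with an estimated correlation). Ciita, the class II transactivator, was 5.93-fold lower, the transcription factor gene Irf8 4.54-fold, the guanylate-binding protein gene Gbp4 5.73-fold and the immunoproteasome subunit gene Psmb8 3.81-fold.

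Erythroid and cell cycle lists rose. All 9 measured erythroid genes rose, also adjusted over the list alone (median 3.54, camera adjusted p = 8.3e-07, adjusted p = 0.350 with an estimated correlation). Hba-a1, an adult alpha globin (chromosome 11, 32283511 to 32284465), stood at 18016 ± 83.7 CPM with elemental diet and 1545 ± 444 with saline, and Hbb-bs, an adult beta globin, at 13737 ± 285 and 971 ± 222. The adult globins have near-identical copies: 25.1% of the Hba-a1 reads and 52.4% of the Hbb-bs reads were unique, and with unique reads the log2 fold change of Hba-a1 was 3.49. Alas2, the erythroid enzyme of the first step in heme synthesis, rose 11.6-fold. All 24 proliferation genes rose, also adjusted over the list alone (median 4.35, camera adjusted p = 3.3e-64, adjusted p = 0.164 with an estimated correlation). Ccna2, cyclin A2, rose 38.9-fold to 506 ± 44.2 CPM, and the mitotic genes Ccnb1, Ccnb2 and Plk1 rose 36.1-fold, 31.6-fold and 29.8-fold. These rises moved together with the higher hemoglobin share and the lower intron share of the elemental diet libraries.

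Of 25 tested genes of fluoropyrimidine and nucleotide metabolism 19 rose and 6 fell, adjusted over the list alone as well (median 2.19, camera adjusted p = 1.8e-13, adjusted p = 0.164 with an estimated correlation). Tyms, thymidylate synthase (chromosome 5, 30058202 to 30073617), stood at 159 ± 3.06 CPM with elemental diet and 9.82 ± 0.441 with saline (log2 fold change 4.02, SE 0.06, adjusted p = 4.2e-15). Dut, the dUTPase that removes dUTP from the nucleotide pool, rose 16.1-fold and Rrm1, the large subunit of ribonucleotide reductase, 15.5-fold. These genes make DNA precursors and are high in dividing cells. The members that fell included Dpyd and Upb1, the first and last enzymes of pyrimidine breakdown, by 1.63 and 2.06 on the log2 scale, named after their values were seen.

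Of 16 tested neutrophil and mast cell genes 12 rose and 4 fell, adjusted over the list alone as well (median 2.81, camera adjusted p = 0.00764, adjusted p = 0.531 with an estimated correlation). S100a8 and S100a9, the calprotectin subunits of neutrophils, rose 16.5-fold and 29.3-fold, and Csf3r, the receptor for granulocyte colony-stimulating factor, 5.59-fold. The 4 that fell, Cma1, Mcpt4, Tpsb2 and Tpsab1, are proteases of tissue mast cells and were named after their values were seen. The other mast cell genes of the list, Cpa3, Fcer1a and Ms4a2, were not among those that fell. With the replicate number as a block the call for this list was lost (adjusted p = 0.121).

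Of the metabolic lists some rose, by less, in the same libraries in which the summed CPM of the erythroid and proliferation lists were 12.0-fold and 17.5-fold higher. Bulk libraries do not separate a change within cells from a change in the mix of cells. All 28 oxidative phosphorylation genes rose, also adjusted over the list alone, with a median log2 fold change of 1.25 (camera adjusted p = 2.5e-12, adjusted p = 0.224 with an estimated correlation). Atp5b, a subunit of ATP synthase, stood at 1463 ± 51.3 CPM with elemental diet and 461 ± 6.95 with saline, and Uqcrfs1 of complex III and Sdhd of complex II rose 3.32-fold and 3.44-fold. Of the 13 mitochondrially encoded transcripts 0 rose and 2 fell, adjusted over the list alone as well, by edgeR's test, and their median turned from 0.01 to -0.30 between scalings, with 12 falling under upper quartile scaling or none, and 2 rising and 2 falling under RLE. Of 29 tested genes of the ATF4 and amino acid response 21 rose and 7 fell, and 21 and 8 adjusted over the list alone (median 1.06, camera adjusted p = 0.000772, adjusted p = 0.350 with an estimated correlation). Mthfd2 and Shmt2, mitochondrial enzymes of one-carbon metabolism, rose 5.53-fold and 3.30-fold and the glycine transporter gene Slc6a9 13.9-fold. Ddit4, a stress-induced inhibitor of mTORC1, fell 4.97-fold. Of 23 cholesterol synthesis genes 19 rose and 2 fell, adjusted over the list alone as well (median 0.84, camera adjusted p = 0.0142, adjusted p = 0.747 with an estimated correlation), with Idi1 at 3.79-fold, Sqle at 3.68-fold, Fdps at 3.32-fold and Cyp51 at 2.58-fold. Glycolysis (10 rose and 9 fell of 19, camera adjusted p = 0.289), fatty acid synthesis (10 and 6 of 21, adjusted p = 0.410) and fatty acid oxidation (11 and 5 of 23, adjusted p = 0.597) were not called by camera, with the same counts adjusted over the list alone. With fry their adjusted p was 0.000635, 4.81e-05 and 0.000137 in this order. For fatty acid oxidation the median was 0.25 and the mean -0.04.

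Of 23 tested genes of the NRF2 antioxidant response 16 rose and 6 fell, adjusted over the list alone as well (median 0.82, camera adjusted p = 0.000453, adjusted p = 0.350 with an estimated correlation). Gpx1, a glutathione peroxidase abundant in red cells, stood at 1700 ± 19.5 CPM with elemental diet and 264 ± 17.9 with saline, and Gclm and Gclc, the subunits of the enzyme that limits glutathione synthesis, rose 9.12-fold and 6.10-fold. Sod1 rose 3.22-fold. Of 19 circadian clock genes 17 fell and 1 rose, adjusted over the list alone as well (median -0.78, camera adjusted p = 0.0334, adjusted p = 0.264 with an estimated correlation). Bhlhe41, Rora, Tef and Clock, all transcription factor genes of the clock, were 3.22-fold, 2.89-fold, 2.54-fold and 1.63-fold lower. This list lost its call without composition normalization (adjusted p = 0.0602) and without saline replicate 2 (0.051) or 3 (0.054).

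**Figure D3:**
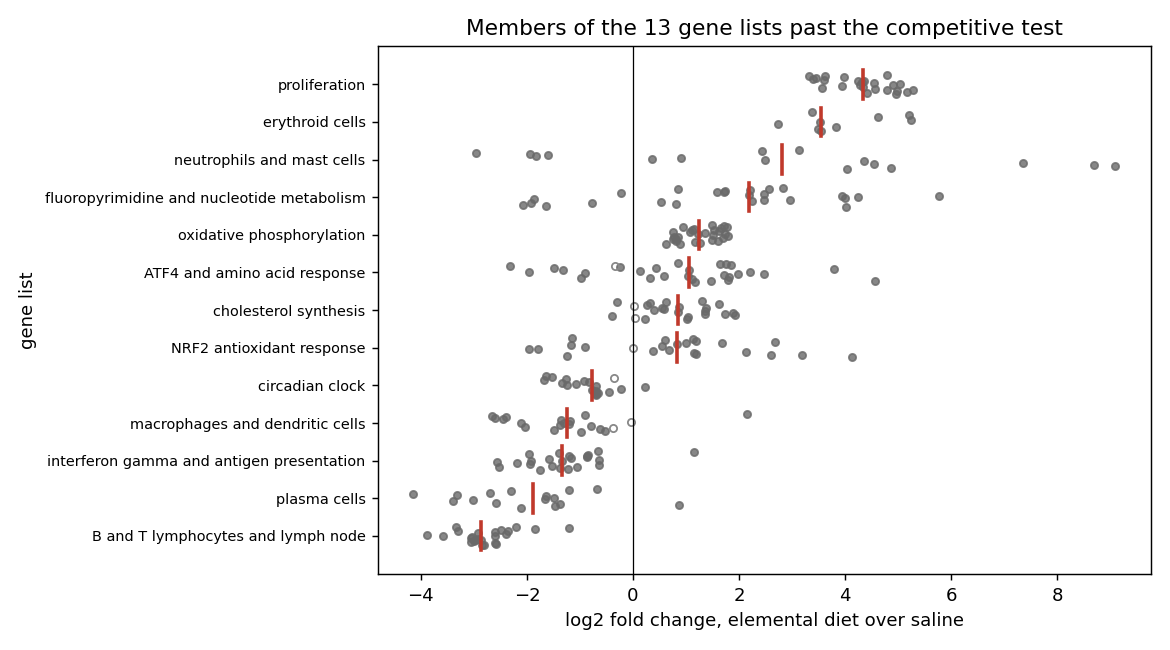
Log2 fold change (elemental diet over saline) of each tested member of the 13 gene lists past the camera test with a preset correlation; filled points passed the test per gene, open points did not, and the red bar is the list median. Medians run from -2.86 for B and T lymphocyte genes to 4.35 for proliferation genes.

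In all, camera with the preset correlation called 13 of 43 lists, 8 higher and 5 lower. With a correlation estimated from the data it called 0, and 8 lists had an unadjusted p under 0.05 there, while fry, which asks whether a list's genes move on balance in either direction without comparing them with other genes, called 37.

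The lists of acinar products, tubule products, fluid secretion, p53 targets and apoptosis regulators were not called by camera. With fry their adjusted p was 0.00557, 0.000207, 0.0518, 0.000831 and 0.000207 in this order. Of the 7 tested acinar secretory products 1 rose and 6 fell, adjusted over the list alone as well (camera adjusted p = 0.650), and with exon reads alone 1 rose and 3 fell. The riser was Ltf, which neutrophils also express, and Pigr and Lyz1 stood at 0.295 and 5.71 CPM with elemental diet and at 1.98 and 12.0 with saline. Oit1 was 5.54-fold lower, from 22 reads against 151, of which 100% and 61.6% lay in introns. Amy1, salivary amylase, stood at 3.59 ± 0.724 and 5.39 ± 0.193 CPM (adjusted p = 0.00921), with 78.1% and 77.8% of its reads in introns, and with exon reads alone its adjusted p was 0.263. Of the 5 tested granular convoluted tubule products 4 fell and 1 did not pass, adjusted over the list alone as well (camera adjusted p = 0.523). Crisp3 stood at 0.633 and 4.26 CPM, Nrg1 at 1.99 and 3.07, and Egf, at 2.97 ± 0.486 CPM with elemental diet, was 1.85-fold lower (edgeR adjusted p = 0.00141). Nrg1 lost its call without elemental diet replicate 2 (adjusted p = 0.122) or 3 (0.0654), and without saline replicate 2 (0.0648) or 3 (0.126).

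Of 23 tested genes of fluid and ion secretion 7 rose and 15 fell, adjusted over the list alone as well (camera adjusted p = 0.659). Kcnn4, a calcium-activated potassium channel also found in red cells and lymphocytes, rose 5.78-fold, and the calcium release channel genes Itpr2 and Itpr3 were 3.43-fold and 5.34-fold lower. Slc4a4, a bicarbonate transporter gene, was 4.78-fold higher, but 99.3% and 91.9% of its reads lay in introns, and with exon reads alone its log2 fold change was -1.32 (adjusted p = 0.0437).

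Of 27 p53 target genes 7 rose and 14 fell, adjusted over the list alone as well (camera adjusted p = 0.588). Cdkn1a, the cell cycle inhibitor p21, stood at 127 ± 1.67 CPM with elemental diet and 121 ± 3.14 with saline, a difference that did not pass (log2 fold change 0.07, adjusted p = 0.200) and that changed sign with the scaling. Ckap2 and Gtse1, which also peak in mitosis, rose 11.8-fold and 4.79-fold, and Trp53inp1 and Sesn1 were 2.51-fold and 2.10-fold lower. Of 24 apoptosis regulators 8 rose and 13 fell, adjusted over the list alone as well (camera adjusted p = 0.402). The pro-apoptotic gene Bak1 rose 2.74-fold, and the survival genes Birc3 and Bcl2 were 5.79-fold and 4.86-fold lower. The camera adjusted p of the lists not called ran from 0.0988 to 0.981.

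Among the 5 most abundant genes, the adult globins and Ighm are given above. Eef1a1, a translation elongation factor, stood at 7788 ± 206 CPM with elemental diet and 7164 ± 270 with saline (log2 fold change 0.12, adjusted p = 0.0202), and mt-Co1, a mitochondrially encoded oxidase subunit, at 9229 ± 697 and 8716 ± 447 (log2 fold change 0.08, adjusted p = 0.199). Both changed sign with the scaling.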

Additional observations from a re-analysis of the deposited data

How the results depend on the processing

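Exon reads alone and the removal of hemoglobin and immunoglobulin genes were tried after seeing the data, the rest was planned. The count of changed genes lay between 10787 (stricter filter) and 14942 (no filter) except when tested against a fold change of 1.5 (9294, with 4432 higher and 4862 lower; fewer genes pass by construction), and between 13770 and 14675 with each library left out in turn. Lists called went from 13 to 0 with camera and an estimated correlation (8 at an unadjusted p under 0.05) and to 37 with fry, and stayed at 12 or 13 in the other settings where lists were tested. Of the named genes 4 changed sign; Slc4a4 did so with exon reads, its reads being mostly in introns, and Cdkn1a, mt-Co1 and Eef1a1 moved with upper quartile scaling or none by as much as the median of all genes (-0.08 to -0.35 and -0.39), as such a change of scale does; for their other sign changes the cause was not tested. Log2 fold changes of Cdkn1a, mt-Co1 and Eef1a1 were -0.20, -0.19 and -0.15 with upper quartile scaling, -0.24, -0.23 and -0.19 without composition normalization, -0.0706, -0.0561 and -0.0178 with the stricter filter, -0.36, -0.33 and -0.29 by limma-trend on log2(TPM + 1) and -0.36, -0.33 and -0.29 on log2(TPM + 0.1). With exon reads they were -0.0623 for Cdkn1a and -0.0306 for mt-Co1, and -1.32 for Slc4a4. Over genes and settings 2090 other values kept their direction and call, 14 lost the call and 3 gained it. Medians of the fibroblast, unfolded protein response, amino acid transporter, fatty acid synthesis, fatty acid oxidation, mitochondrially encoded, glycolysis, autophagy, ribosome and junction lists changed sign between scalings. Deviations of libraries with the same replicate number correlated at 0.117, -0.008 and 0.058. Not every library correlated best with its own number, so the numbers were not taken as pairs. Against this, the second principal component fell from replicate 1 to 3 in both groups, and Car3, given below, was highest in replicate 1 of both. With the replicate block 14241 genes and 12 lists were called. Library totals overlapped between groups, the TMM factors did not (0.881 to 0.926 and 1.11 to 1.12), and depth let only genes with enough reads be tested, such as 7 of 27 acinar products.

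The 6 libraries can be split into 3 and 3 in 10 ways, too few for a share under 0.05. The real split gave 14303 changed genes, so 1 of 10 splits gave as many, and the highest of the others gave 0 by edgeR's test, where at most 121 genes had an unadjusted p under 0.05.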

Other observations

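All tests in this part, and the lists of erythroid precursor, megakaryocyte, myeloid progenitor, spleen and other organ genes, were chosen after the data were seen. All 29 genes of nucleated erythroid precursors, none of them in a list fixed beforehand, rose by a median of 4.07 on the log2 scale (camera adjusted p = 3.7e-51, adjusted p = 0.107 with an estimated correlation). Among them were Car1, the most abundant, at 1761 ± 131 CPM (SD, n = 3) against 66.1 ± 1.11, Klf1, a master transcription factor of red cell development, at 538 ± 7.69 against 9.71 ± 1.27 and Tfrc, the transferrin receptor, at 1456 ± 89.8 against 48.6 ± 4.83 CPM. Besides red cell genes, other blood-forming lineages were higher with elemental diet. All 17 megakaryocyte and platelet genes rose (median log2 fold change 1.65, camera adjusted p = 2.5e-05, adjusted p = 0.360 with an estimated correlation), 1 of them also in a list fixed beforehand. Ppbp, a platelet chemokine, stood at 2574 ± 340 CPM (SD, n = 3) with elemental diet and 743 ± 39.1 with saline, and Itga2b, the platelet integrin CD41, at 674 ± 72.8 and 277 ± 5.39. Of 13 genes of myeloid progenitors and basophils 12 rose and 1 fell (median 3.42, camera adjusted p = 4.5e-05, adjusted p = 0.124 with an estimated correlation), 5 of them also in a fixed list. Prtn3, proteinase 3, was 10.6-fold higher than its saline level of 2.35 ± 0.167 CPM, and Ms4a3, a marker of granulocyte precursors, stood at 6.86 ± 0.862 and 0.455 ± 0.237. Embryonic beta-like globins followed the embryonic alpha-like Hba-x: Hbb-y had 594 reads with elemental diet against 13 with saline, and Hbb-bh1 111 against 9. These counts include reads shared between genes. The share of unique reads was not computed for Hbb-y and Hbb-bh1, so a part from the abundant adult globins cannot be told apart.

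The libraries labelled salivary gland held almost no gland transcripts. Loss of acinar cells from a gland that keeps its ducts and myoepithelium is argued against, because 0 of 10 epithelial genes (Krt5, Krt7, Krt8, Krt14, Krt18, Krt19, Epcam, Cdh1, Cldn4, Cldn7) lay above the 18.3 CPM of the median tested gene in either group. Reads of secretory genes lost because they map to several places are argued against by Aqp5, with 6 reads over the 6 libraries when shared reads are counted. A candidate explanation is that the libraries come from spleen and not from a salivary gland. All 18 genes of spleen stroma, marginal zone and red pulp, 4 of them also in a fixed list, were at 1 CPM or more in every library. Of the acinar products 3 of 27 were. All 24 members of the B and T lymphocyte and lymph node list reached this level too, so the count cannot tell spleen from lymph node. Of the 18 spleen genes 17 fell with elemental diet (camera adjusted p = 4.4e-07, 0.107 with an estimated correlation). The most abundant of them, Cr2 and Ighd, are also B cell genes and stood at 152 ± 3.62 and 106 ± 3.86 CPM with elemental diet and at 1213 ± 27.8 and 1155 ± 44.7 with saline; Tlx1 and Nkx2-3, transcription factors of spleen development, stood at 18.8 ± 2.29 and 13.6 ± 3.10 CPM with elemental diet and at 37.6 ± 0.938 and 24.0 ± 2.55 with saline, while bone marrow stroma, thymocyte and hepatocyte lists had 2 of 12, 4 of 10 and 1 of 12 genes at 1 CPM in every library.

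Erythroid and cell cycle genes were higher and lymphoid genes lower with elemental diet. Circulating blood left in the tissue brings hemoglobin but few cell cycle transcripts. As the only cause it is argued against by the median log2 fold change of 4.35 in the proliferation list. That list is itself part of the pattern, so blood as the source of a part of the hemoglobin share stays open. A loss of lymphocytes that raises every other cell type alike is argued against by the gap of 4.56 on the log2 scale between the medians of erythroid precursors (4.07, quartiles 3.14 to 4.90) and of endothelium and pericytes (-0.49, quartiles -0.78 to 0.14). The precursor list was drawn up after the data were seen, but the erythroid list fixed beforehand had a median of 3.54. The choice among the 5 scalings tried is argued against, as the lymphocyte median stayed at -2.81 or lower and the erythroid median at 3.23 or higher. These scalings moved the median of all genes only between -0.04 and -0.39, too little to turn medians of that size. All 5 are relative, so absolute amounts of transcript were not measured. Whether the elemental diet alone is behind these changes cannot be told. The series holds 0 libraries from mice without 5-FU or from a second set of mice per diet. Diet and any other difference between the 2 sets of mice therefore cannot be told apart. The sets also differed in V gene usage, described in the next paragraph. Of 178 V genes 26 to 31 differed over 8-fold in usage between libraries of different groups, and 0 within a group. The diet was thus not shown to be the only difference.

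Replicates were nearly alike within groups, though not in every gene (Car3, given below), while the usage of immunoglobulin V genes was far apart between groups. For example, chosen after their values were seen, Ighv1-34 (chromosome 12, 114851190 to 114851660) had 10 reads with elemental diet and 8255 with saline, although Ighv9-3 (chromosome 12, 114140692 to 114141122) had 886 and 11. That one library was deposited more than once is argued against by the smallest median chi-square between 2 replicates, 2.97 times sampling noise. Fewer B cells lowering all V genes alike is argued against by the SD of log2 usage ratios, at least 1.43 between groups and at most 0.58 within over the 111 V genes with at least 100 reads in each group (2.39 and 0.74 over 178 V genes). What remains is that 1 animal or 1 pool of animals may stand behind the 3 libraries of each group. Between 2 libraries of a group 0 of 178 V genes differed over 8-fold in usage, against 26 to 31 between groups. For the 111 V genes the counts were 0 against 4 to 7. Counts under 3 were taken as 3, so V genes with few reads in both libraries could not reach 8-fold. The counts include reads shared between V genes, and usage was not computed from unique reads. Among V genes with at least 100 reads in 1 of the 2 libraries, 0 differed as well. There were 78 to 84 of these with elemental diet and 169 to 172 with saline. Separate outbred mice with different V gene haplotypes would not be likely to give this, while mice of like haplotype within each group stay open. With 1 such source per group, the SD and p-values above measure the spread between its libraries and not between mice.

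In the TRIM cluster on chromosome 7 (104218793 to 104507849), 10 of 12 tested genes were lower with elemental diet and 2 were higher. Log2 fold changes of the Trim genes that fell ran from -4.37 for Trim5 to -0.68 for Trim34b, while Trim12c was higher, at 1.11, as was the predicted gene Gm15133, at 1.98. Car3, a carbonic anhydrase abundant in adipocytes, stood at 73.7, 3.81 and 3.75 CPM in the elemental diet replicates and at 46.9, 1.11 and 1.08 in the saline replicates. For this gene the replicates were not alike, with replicate 1 highest in both groups. Whether handling by replicate number stands behind this was not tested. Housekeeping genes were higher in 9 and lower in 2 of 12 cases (median 0.51), and 7 and 4 without composition normalization (median 0.20).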
